A study of Drosophila melanogaster with 4 samples.

How the data were processed

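The data were 4 ribosome footprint libraries from Drosophila melanogaster ovaries, 2 from wildtype females and 2 from RpS5b mutant females. Ribosome footprinting sequences the short RNA fragments that a ribosome shields from nuclease, so a count per gene combines how much of its mRNA is present with how densely that mRNA is occupied by ribosomes. Per the labels' protocols, ovaries were dissected by hand 48 hours after the adults emerged, egg chambers of stages 10 to 14 were taken out of the control ovaries, fragments of 28 to 34 nt were selected on a gel, and ribosomal RNA was depleted. Per the submitters' processing notes, the tools included Bowtie 1.0.0, TopHat2 2.1.2, SAMtools 0.1.19, bedtools 2.26.0 and DESeq2, and the genome build was BDGP6. The role of each tool is not given in the sources used here. No RNA-seq libraries were used here, so no translational efficiency was computed.

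The authors deposited 1 table per library with 34729 annotated transcripts. Per the file headers, each count is the number of reads of 25 to 100 nt whose position, set 12 nt from the 5' end of the read, lies in a transcript. Whole transcripts with their untranslated regions were counted, and no region was masked. The deposited RPKM column is the count per kilobase of transcript and scaled to the reads of the library. The deposited signal column, the mean coverage per nucleotide, is the count divided by the transcript's length, and a further deposited column gives that length. Only the counts were tested. The tables hold 1 total per transcript and no positions, so the distribution of footprints along genes, which the series' design names, could not be compared.

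A read was counted in each transcript that overlaps it, and near-identical transfer RNA genes had near-identical counts, so counts summed over the isoforms of a gene would count reads repeatedly. The transcript with the highest mean count over the 4 libraries therefore stands for its gene. Transcripts were tied to gene names by their coordinates in a RefSeq gene table of the same genome release, through shared ends, splice junctions or an overlap of at least 80% both ways. This named 34615 of the 34729 transcripts (99.7%), in 17435 genes or joint loci, of which 13729 were protein-coding. At 168 loci 2 or more genes have the same span and are named jointly, such as CG45087/Pepck1. The other 114 transcripts held between 0.073% and 0.099% of a library's reads and were left out of the library sizes and the tests. Overlapping genes and near-identical copies can share reads, and values of such genes are uncertain.

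Genes were kept by edgeR's filterByExpr with the groups, which left 7782. Libraries were scaled by TMM, and each gene was tested with edgeR's quasi-likelihood test (version 4.0.16, in R 4.3.3) with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called changed at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p under 0.333, so the calls rest on the spread that the model shares between genes, with 2 residual and 5.52 prior degrees of freedom. No label says that the libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Library totals, as the file headers give them, lay between 3122299 and 13942184 reads. Footprints have no molecular identifiers, so repeated reads of 1 fragment are counted as separate.

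A set of 25 gene lists, 5 of them markers of other cell types, was fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The cytoplasmic and mitochondrial ribosomal protein, translation factor, oxidative phosphorylation and proteasome lists were defined by patterns in gene symbols, and the others gene by gene. Older symbols were updated through the RefSeq table. Lists with at least 3 measured members, 23 in all, were tested with camera (limma 3.58.1) at an inter-gene correlation preset at 0.01, with Benjamini-Hochberg adjustment over the lists. The markers of nerve and trachea had 2 measured members and those of gut fewer than 3, and neither was tested. Camera with an estimated correlation and fry were alternatives. The rule named RpS5b and RpS5a, then per direction the 10 genes with the largest log2 fold change among those with an adjusted p under 0.05, a mean CPM (counts scaled to a common library size, as edgeR defines it) of at least 10 and ranges of the groups that did not overlap. From each list it named up to 2 members per direction with the smallest p and a mean CPM of at least 10. Genes named outside this rule are said to be chosen after their values were seen.

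The same functions were tested on simulated counts for 7782 genes with the means, the trend of the dispersions and the library sizes of these 4 libraries. Of 50 simulated genes at each size, the test recovered 68% at a log2 change of 1, 90% at 1.5, 94% at 2 and 100% at 3. It called 13 of 7522 unchanged genes, 6.47% of all its calls. Each simulated gene took the trend's dispersion at its mean, without a gene-specific spread. Far fewer genes were changed than the 3221 called in the data, which makes the adjusted threshold stricter. The share recovered and the share of wrong calls therefore need not hold for these data. A list raised by 0.7 had a camera p of 1.9e-20, and 0 of 20 unchanged lists reached an unadjusted p under 0.05. Simulated genes were drawn independently of each other, whereas the estimated correlation was 0.757 for the cytoplasmic ribosomal protein genes. The simulation therefore does not test camera's p-values for lists whose genes vary together. The alternatives were other scalings (DESeq2's median of ratios, total counts, upper quartile, and TMM without the ribosomal protein, yolk, vitelline membrane and chorion genes), other filters, the replicate number as a block, each library left out, the DESeq2 Wald test (version 1.42.0), limma-voom, other thresholds, and transcripts summed or tested singly. Protein-coding genes alone and libraries thinned to 1 total were alternatives chosen after the data were seen. A planned change of pseudocount did not apply, since the values are counts.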

Results

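Ribosome footprints were counted in 4 libraries from Drosophila ovaries, 2 from wildtype females and 2 from females mutant for RpS5b. RpS5b encodes one of a pair of paralogs of the small-subunit ribosomal protein S5 in this fly, and RpS5a encodes the other. The wildtype libraries held 3122299 and 6170623 reads and the mutant libraries 13942184 and 8714570. Transfer RNA genes took between 54.8% and 63.94% of the counts over genes. Protein-coding genes held 1053507 and 1738166 counts in the wildtype and 4600027 and 3066456 in the mutant libraries, so low genes were measured more precisely in the mutant. Per the labels, egg chambers of stages 10 to 14 had been removed from the control ovaries. The comparison asks how ribosome footprints per gene differed between mutant and wildtype ovaries.

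RpS5b, the mutated gene, had 287 and 342 footprint counts in the wildtype libraries and 10 and 9 in the mutant libraries. In CPM, scaled counts relative to library size, this was 78.0 ± 21.1 (SD, n = 2) against 0.906 ± 0.181 (SD, n = 2), a log2 fold change of -6.43 (SE 0.29, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.56e-05). The counted transcript lies on chromosome 3R at 14900432 to 14901563 of build BDGP6, on the minus strand. Its paralog RpS5a, on chromosome X at 17143588 to 17148264, rose from 38.8 ± 7.88 to 110 ± 38.4 CPM (SD, n = 2 each), a log2 fold change of 1.52 (SE 0.26, edgeR adjusted p = 0.00329). The rise of RpS5a lay between the quartiles, 1.22 and 1.64, of 83 other cytoplasmic ribosomal protein genes, so it did not stand out from theirs. Reads that the paralogs could share were not resolved by the counting.

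Of 7782 genes tested, 1594 were higher and 1627 lower in the mutant libraries at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At least a doubling was called for 637 genes and at least a halving for 874. The CPM of the groups did not overlap for 71.8% of the genes, where chance gives 33.3%. The call counts depended on depth: after thinning the libraries to 1 total, an alternative chosen after the data were seen, 719 genes were higher and 837 lower. The DESeq2 Wald test called 852 higher and 1135 lower. Without wildtype replicate 2, 1032 genes were higher.

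**Figure D1:**
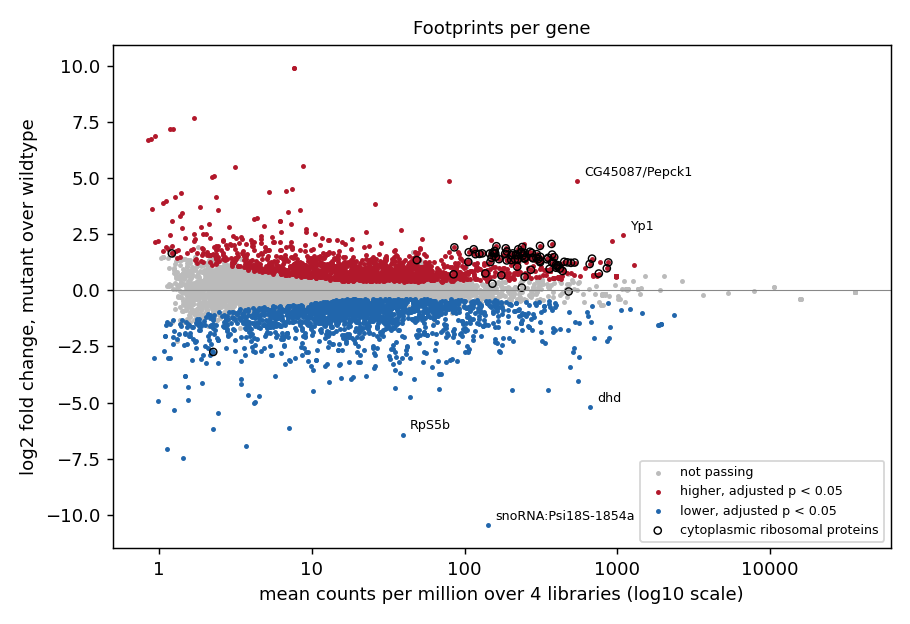
Each point is 1 of 7782 genes, with its mean CPM over 4 libraries on a log10 scale and the log2 fold change of mutant over wildtype, coloured by the edgeR call at an adjusted p under 0.05. Circled cytoplasmic ribosomal protein genes lie mostly above 0 (79 of 83 higher), and RpS5b, at -6.43, is among the lowest points.

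Among the 10 largest rises that met the naming rule were CG45087/Pepck1, Cda5, Lip4 and Yp1. The locus CG45087/Pepck1, where 2 genes share 1 span and one encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose from 36.3 to 1055 CPM, a log2 fold change of 4.85 (SE 0.23). Cda5, a chitin deacetylase-like gene, rose by 3.82 on the log2 scale (SE 0.19), Yp1, a yolk protein, by 2.45 (SE 0.29), and the lipase gene Lip4 by 2.37 (SE 0.18). The others were snoRNA:Psi18S-1347b at 4.87, CG12398 at 2.68, CG6891 at 2.61, CG17124 at 2.51, CG15096 at 2.35 and CG44085 at 2.30. The 10 largest falls included RpS5b. The thioredoxin gene dhd fell from 1298 to 35.2 CPM, a log2 fold change of -5.21 (SE 0.24). A subunit gene of a kinase of egg activation, gnu, was at -4.78 (SE 0.17), mtrm, an inhibitor of Polo kinase in meiosis, at -4.42 (SE 0.18) and the cyclin gene CycB3 at -4.37 (SE 0.17). The small heat shock protein gene Hsp27 was at -4.45 (SE 0.27), CG12716 at -4.47, superdeath at -4.42 and CG7730 at -4.08. A small nucleolar RNA, snoRNA:Psi18S-1854a, had 1056 and 1239 counts in the wildtype against 4 and 0 in the mutant libraries. Related snoRNAs beside it, given below, did not pass, and snoRNA fragments need not come from ribosomes. Each of the 10 rises and 10 falls had an edgeR adjusted p of 0.000743 or lower. They kept their direction and call in each alternative in which named genes were followed, 15 for most and 14 for the snoRNAs.

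**Figure D2:**
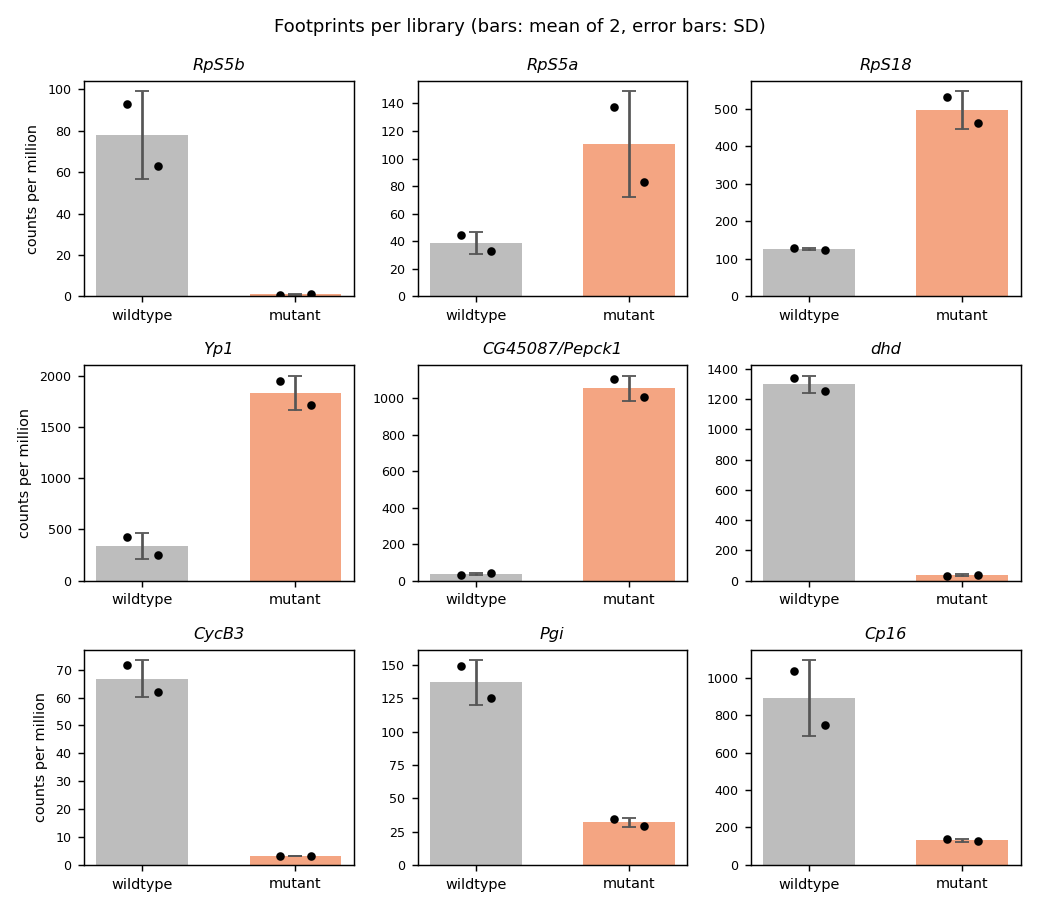
CPM of 9 genes, with points for the 2 libraries of each group, bars for their mean and error bars for the SD. RpS5b, dhd, CycB3, Pgi and Cp16 were lower in both mutant libraries than in both wildtype libraries, and RpS5a, RpS18, Yp1 and CG45087/Pepck1 were higher.

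Genes of the cytoplasmic ribosome rose together. Of 83 measured cytoplasmic ribosomal protein genes, 79 rose, 1 fell and 3 did not pass, the same counts when adjusted over the list alone, with a median log2 fold change of 1.42 (camera adjusted p = 9.0e-24, and adjusted p = 0.44 with an estimated correlation). RpS18 rose from 126 to 497 CPM, a log2 fold change of 1.98 (SE 0.17). RpL9 was at -0.055 (SE 0.17, edgeR adjusted p = 0.82), RpS2 and sta also did not pass, and RpS10a, a gene with few counts, fell. Without wildtype replicate 2 the call of RpS10a was lost over all genes but not over the list alone. The list's median was then 1.33, and that of the paralogs below 1.27. Of 21 ribosomal protein paralogs measured, 20 rose and 1 fell, also when adjusted over the list alone, with a median of 1.40 (camera adjusted p = 8.5e-08, and adjusted p = 0.44 with an estimated correlation). All of these paralogs but RpS5a, RpL24-like, RpL7-like and RpLP0-like are also in the first list, so this is largely the same result. RpS15Aa was at 1.75 (SE 0.19) and RpL34a at 1.34 (SE 0.16), and near-identical copies such as RpS14a and RpS14b can share reads. Chorion genes of late egg chambers moved the other way in the same libraries, with a median of -1.95.

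Genes that build ribosomes also rose. Of 57 ribosome biogenesis and RNA polymerase I genes, 39 rose and 3 fell (49 and 3 when adjusted over the list alone), with a median of 0.72 (camera adjusted p = 5.3e-08, and adjusted p = 0.32 with an estimated correlation). Surf6 rose by 1.60 on the log2 scale (SE 0.14) and the kinase gene RIOK1 by 1.27 (SE 0.13). The 3 that fell were Rrp1 at -1.13 (SE 0.19), Uba2 at -0.88 (SE 0.14) and Nop17l at -0.75, the last chosen after its value was seen; Rrp1 encodes a DNA repair nuclease and Uba2 a subunit of the SUMO-activating enzyme. Of 45 translation initiation and elongation factors, 20 rose and 1 fell (21 and 1 when adjusted over the list alone), with a median of 0.51 (camera adjusted p = 6.9e-04, and adjusted p = 0.55 with an estimated correlation). The initiation factor gene eIF3k was at 1.34 (SE 0.17) and eIF6 at 1.03 (SE 0.14), while eIF2A fell to -0.95 (SE 0.16) and eIF4E1 was at -0.29 (adjusted p = 0.18, edgeR). The factors that rose numbered 11 without wildtype replicate 2 and 12 without mutant replicate 1 or after thinning. Of 73 mitochondrial ribosomal protein genes, 21 rose and 0 fell (14 and 0 when adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.00148, and adjusted p = 0.38 with an estimated correlation). In that list mRpL39 was at 1.21 (SE 0.15) and mRpS17 at 0.69 (SE 0.13), and mRpL46 at -0.51 and mRpL3 at -0.23 did not pass. The call of mRpS17 was lost in 2 of 15 alternatives, and the genes of this list that rose numbered 8 without wildtype replicate 2 (where 1 fell), 10 without mutant replicate 1 and 3 after thinning (0 over the list alone).

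**Figure D3:**
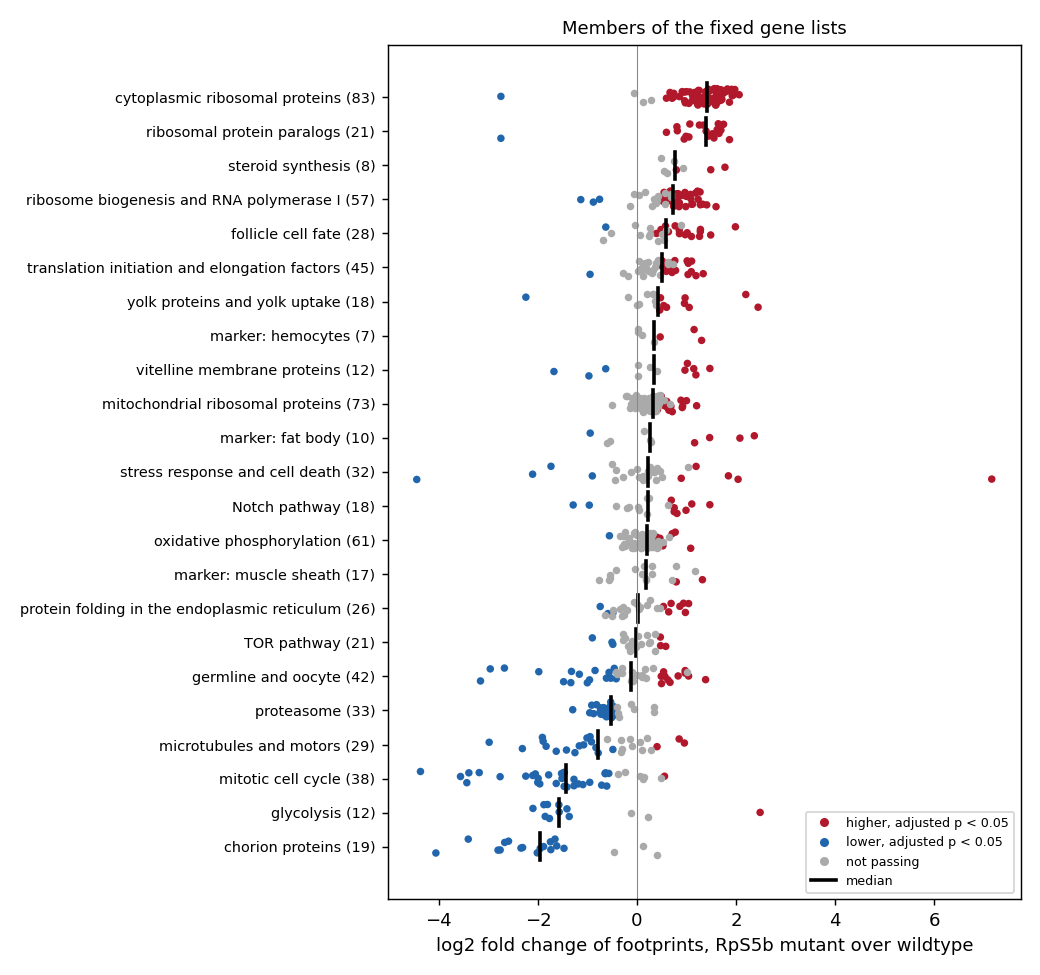
Log2 fold change of mutant over wildtype for the measured members of 23 gene lists (numbers of members in brackets), with a black line at each list's median and colours for the edgeR call of each gene. Medians run from -1.95 for the chorion proteins to 1.42 for the cytoplasmic ribosomal proteins.

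Genes of sugar breakdown and of the proteasome fell. Of 12 glycolysis genes, 9 fell, 1 rose and 2 did not pass, also when adjusted over the list alone, with a median of -1.57 (camera adjusted p = 1.6e-05, and adjusted p = 0.44 with an estimated correlation). Pgi, which encodes glucose-6-phosphate isomerase, fell from 137 to 31.8 CPM, a log2 fold change of -2.10 (SE 0.16), and the phosphofructokinase gene Pfk was at -1.85 (SE 0.13). Hex-A was at 0.23 (edgeR adjusted p = 0.24), and Ldh, lactate dehydrogenase, chosen after its value was seen, rose from 0.531 to 3.32 CPM. Of 33 proteasome genes, 26 fell and 0 rose (28 and 0 when adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.00276, and adjusted p = 0.54 with an estimated correlation). The proteasome genes that fell numbered 11 without wildtype replicate 1, 12 without mutant replicate 1 and 14 without mutant replicate 2, 9 with scaling by total counts (7 over the list alone) and 10 after thinning. Prosbeta1 was at -1.30 (SE 0.15) and Prosalpha6 at -0.91 (SE 0.15). Prosalpha1 and Prosalpha1R, which had the same counts because they share reads, were at 0.35 (adjusted p = 0.098). Of 61 nuclear genes of oxidative phosphorylation, 9 rose and 1 fell (3 and 0 when adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.11). Without mutant replicate 2 camera called this list at an adjusted p of 0.0370, while the genes that rose numbered 5 with either wildtype library left out, 3 without mutant replicate 1 and 3 after thinning, and 0 fell with any library left out. The median was 0.11 without wildtype replicate 2 and 0.12 without mutant replicate 1. Cyt-c-p was at 1.08 (SE 0.14) and ND-AGGG at 0.71 (SE 0.14), while COX4 at -0.34 did not pass. The ATP synthase gene blw, at -0.56 (SE 0.19), lost its call in 7 of 15 alternatives, among them each that left out 1 library.

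Stress genes went both ways. Of 32 stress response and cell death genes, 5 rose and 4 fell, also when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.36). Without mutant replicate 2, 9 genes of this list fell and the median was 0.090. Gadd45 was at 2.04 (SE 0.16) and puc, a phosphatase gene of the JNK pathway, at 1.19 (SE 0.14), against -4.45 for Hsp27 and -1.74 (SE 0.17) for the glutathione transferase gene GstD1. Of 26 genes of protein folding in the endoplasmic reticulum, 7 rose and 3 fell (9 and 4 when adjusted over the list alone), with a median of 0.023 (camera adjusted p = 0.36). The translocon gene Sec61gamma was at 1.04 (SE 0.14) and the transcription factor gene Xbp1 at 0.94 (SE 0.13). The median turned to -0.022 without wildtype replicate 2 and -0.044 without mutant replicate 1, was 0.071 without wildtype replicate 1 and 0.014 without mutant replicate 2, and 1 gene fell with either wildtype library left out. Uggt at -0.59 and Sil1 at -0.74 lost their calls in 4 and 5 of 15 alternatives, both without mutant replicate 1, Uggt also without wildtype replicate 1 and Sil1 without wildtype replicate 2. Of 21 TOR pathway genes, 3 rose and 3 fell (2 and 2 when adjusted over the list alone). The median was -0.026 while camera's direction was up (adjusted p = 0.82), and it was 0.048 without wildtype replicate 2. Only 1 gene rose with wildtype replicate 1, wildtype replicate 2 or mutant replicate 1 left out, and 1 fell with wildtype replicate 1 or mutant replicate 1 left out. Here foxo was at 0.58, PRAS40 at 0.47, rictor at -0.50 and mTor at -0.49, with calls lost in 2, 6, 5 and 6 of 15 alternatives. Those of PRAS40, rictor and mTor were lost without wildtype replicate 1 or mutant replicate 1, and that of PRAS40 also without wildtype replicate 2.

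Chorion genes fell while yolk protein genes rose. Of 19 chorion protein genes, 16 fell, 0 rose and 3 did not pass, also when adjusted over the list alone, with a median of -1.95 (camera adjusted p = 2.8e-13, and adjusted p = 0.38 with an estimated correlation). Cp16 fell from 894 to 132 CPM, a log2 fold change of -2.76 (SE 0.22), and Mur11Da was at -2.81 (SE 0.19). The eggshell gene dec was at 0.41 and Cad99C at 0.13, and neither passed. Of 12 genes of the vitelline membrane, an eggshell layer made earlier than the chorion, and related genes, 5 rose and 3 fell, also when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.30). The median was 0.64 without wildtype replicate 1, 0.20 without wildtype replicate 2 and 0.16 without mutant replicate 1. The rises included ndl at 1.47 (SE 0.16) and psd at 1.19 (SE 0.14), and the falls Fcp3C at -1.68 (SE 0.22) and fs(1)N at -0.97 (SE 0.15). Of 18 yolk protein and yolk uptake genes, 9 rose and 1 fell (11 and 1 when adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0272, and adjusted p = 0.44 with an estimated correlation). The list's camera call was also lost with the stricter filter of 10 CPM in 2 libraries (camera adjusted p = 0.0591) and without wildtype replicate 2 (median 0.42). Yp1 rose from 337 ± 124 to 1836 ± 166 CPM (SD, n = 2 each) and Yp2 by 2.20 on the log2 scale (SE 0.28), while yl, the yolk protein receptor of the oocyte, fell to -2.24 (SE 0.19). Moe was at -0.19 and did not pass.

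Cell cycle genes fell. Of 38 mitotic cell cycle genes, 31 fell, 1 rose and 6 did not pass, also when adjusted over the list alone, with a median of -1.44 (camera adjusted p = 7.0e-23, and adjusted p = 0.32 with an estimated correlation). CycB3 fell from 66.8 to 3.20 CPM and the kinase gene aurA was at -3.39 (SE 0.15). The one rise, pav at 0.56 (SE 0.13), was lost in 4 of 15 alternatives, among them those without wildtype replicate 1, wildtype replicate 2 or mutant replicate 2, and dap at 0.14 did not pass. Several members, CycB3 among them, also act in meiosis and the early embryo, and the chorion genes fell in the same libraries with a median of -1.95. Of 29 genes of microtubules and motors, 16 fell and 3 rose, also when adjusted over the list alone, with a median of -0.78 (camera adjusted p = 6.8e-05, and adjusted p = 0.33 with an estimated correlation). The kinesin-like gene nod was at -2.98 (SE 0.17) and the stathmin gene stai at -2.31 (SE 0.16), against 0.96 (SE 0.15) for betaTub60D. The rise of shot, at 0.41, was lost in 9 of 15 alternatives, among them each that left out 1 library, and without mutant replicate 1 only 1 gene of the list rose. Of 42 germline and oocyte genes, 11 rose and 16 fell (11 and 17 when adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.15). Without wildtype replicate 2, 5 rose and the median was -0.18 (camera adjusted p = 0.0559), without wildtype replicate 1, 10 fell, and without mutant replicate 1 the median was -0.21. The piRNA pathway genes del and shu were at 1.04 (SE 0.15) and 0.97 (SE 0.13). Pxt, an oxygenase-like gene needed in follicle development, fell from 990 to 127 CPM, a log2 fold change of -2.96 (SE 0.20), and swa, which acts in bicoid RNA localisation, was at -2.68 (SE 0.20).

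Genes of the follicle cell fate list rose more often than they fell. Of 28 follicle cell fate genes, 15 rose and 1 fell (16 and 2 when adjusted over the list alone), with a median of 0.58 (camera adjusted p = 6.8e-04, and adjusted p = 0.33 with an estimated correlation). The transcription factor gene br was at 1.49 (SE 0.18) and the receptor gene Egfr at 1.26 (SE 0.15). After thinning 8 genes of the list rose. A fall of usp, at -0.63, was lost in 4 of 15 alternatives, among them those without wildtype replicate 2 or mutant replicate 2, and ftz-f1 at -0.52 did not pass. Of 18 Notch pathway genes, 7 rose and 2 fell, also when adjusted over the list alone, with a median of 0.22 (camera adjusted p = 0.22). The receptor gene N was at 0.81 (SE 0.14) and peb at 0.75 (SE 0.13), against -1.29 (SE 0.15) for O-fut1, while H at -0.43 did not pass. The fry test called this list (adjusted p = 0.020). With any 1 library left out only 1 gene of it fell, and after thinning 4 rose. Of 8 genes of steroid synthesis, 3 rose and 0 fell, also when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.0190, and adjusted p = 0.38 with an estimated correlation). The sterol transporter gene Npc1a was at 0.80 (SE 0.13) and Npc2a at 0.55 did not pass. With the stricter filter of 10 CPM in 2 libraries the steroid list's call was lost at an adjusted p of 0.0785, and after thinning at 0.0619. With scaling by total counts 5 of its genes rose (7 over the list alone).

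Markers of the ovary's muscle sheath and of tissues that can adhere to ovaries were measured beside these lists. Of 17 muscle sheath genes, 2 rose and 0 fell (0 and 0 when adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.45). The median turned to -0.065 without wildtype replicate 2, where 1 rose, and to -0.12 without mutant replicate 1, where 3 fell, and was 0.35 without wildtype replicate 1. With the replicate block 5 rose and 3 fell. The titin-like genes sls, at 1.32, and bt, at 0.79, lost their calls in 2 and 5 of 15 alternatives, sls without either of the wildtype libraries in turn and bt without wildtype replicate 2 or mutant replicate 2, and the actin genes Act87E at -0.57 and Act57B at -0.41 did not pass. Of 10 fat body genes, 4 rose and 1 fell, also when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.089). Lip4 and the perilipin gene Lsd-1, at 1.47 (SE 0.14), rose, Mtp was at -0.94 (SE 0.20) and lost its call in 1 of 15 alternatives, and Cyp4g1 at -0.55 did not pass. Camera called the fat body list at an adjusted p of 0.0321 without wildtype replicate 1 (median 0.51) and 0.0186 without mutant replicate 2 (median 0.60). The median was 0.10 without wildtype replicate 2, and 2 genes fell there and without mutant replicate 1. Of 7 hemocyte genes, 3 rose and 0 fell, also when adjusted over the list alone, with a median of 0.34 (camera adjusted p = 0.14). Those with the smallest p were the collagen IV genes vkg at 1.30 (SE 0.16) and Col4a1 at 1.15 (SE 0.17), which follicle cells also express. The fry test called the hemocyte list (adjusted p = 0.027), whose median was 0.20 without wildtype replicate 2, 0.21 without mutant replicate 1 and 0.20 without mutant replicate 2.

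The libraries of a group resembled each other more than those of the other genotype. Across the 7782 genes, which are not independent replicates, the Spearman correlation of log2 CPM was 0.974 between the wildtype and 0.985 between the mutant libraries, and between 0.885 and 0.901 across genotypes. The first principal component held 81.9% of the variance and separated the genotypes.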

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

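Transcripts that matched no gene were left out of the comparison and were tested beside it, a test chosen after the data were seen. Of 114 such transcripts, reduced to 77 groups without overlap, 20 had enough counts, of which 4 were higher and 5 lower in the mutant libraries at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The one that was higher with a mean CPM of at least 10, a floor added after 4 had been seen, FBtr0079217 on chromosome 2L at 6046654 to 6047934, had a log2 fold change of 1.08 (SE 0.16, edgeR adjusted p = 0.00178). It was singled out as a signal above the control in data that the comparison does not use. It overlaps the genes slmo and CG34179, and its counts, 36 and 51 in the wildtype and 292 and 180 in the mutant, equal those of slmo in each library, so they are reads already counted there.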

How the results depend on the processing

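None of the named genes that passed the threshold turned in direction, and counts of calls moved with depth and threshold. Of 101 named genes, 83 passed the threshold, and 69 of them passed it in each alternative in which they were followed, 15 for most and 14 for the 2 snoRNAs. Named genes were not followed with limma-voom, with transcripts tested singly or at other thresholds. The rest lost their call in at least 1, and 10 of the 18 that had not passed did so in at least 1. Against 3221 changed genes (1594 higher, 1627 lower), thinning the libraries to 2939745 counts gave 1556 (719 and 837), of which 1528 were shared in direction, the DESeq2 Wald test 1987 (852 and 1135), and a required doubling or halving 1511 (637 and 874); fewer counts, and a stricter rule by its construction, account for the first and last, and for DESeq2 the cause was not tested. Leaving out each library gave 2213 to 2944 changed genes, with 1032 to 1410 higher, fewer samples by construction; the lone library of a group is then assumed to vary like the others. With the replicate block 3838 genes were changed and 13 lists passed. Same-numbered libraries deviated together (correlation 0.25 over all genes, 0.46 over those of at least 10 CPM), but 2 pairs and no label do not show that the numbers pair them. Camera called 13 lists and, with an estimated correlation, 0, at medians of 1.42, 1.40, 0.33, 0.72, 0.51, -1.57, -0.53, 0.42, -1.95, -1.44, 0.58, -0.78 and 0.77 that do not depend on it, and at unadjusted p-values under 0.05 for ribosome biogenesis (0.019) and the cell cycle (0.028); fry called 13 of its own. With fry the ribosomal protein paralogs (median 1.40, adjusted p = 0.059) and translation factors (0.51, adjusted p = 0.094) did not pass, the Notch (adjusted p = 0.020) and hemocyte lists (adjusted p = 0.027) did, and the TOR median of -0.026 went with a direction opposite to camera's. The filter of 10 CPM ended the calls of the yolk (median 0.45) and steroid lists (0.67), thinning that of the steroid list (0.65), and leaving out wildtype replicate 2 that of the yolk list (0.42, and 0.47 without wildtype replicate 1 and 0.39 without mutant replicate 2); the cause was not tested. Values with no call that turned included the TOR median (0.032 with total counts, 0.0081 with the upper quartile, 0.048 without wildtype replicate 2, 0.097 thinned and 0.029 over members of at least 10 CPM), that of folding in the endoplasmic reticulum (-0.0091 with DESeq2's scaling, -0.022 without wildtype replicate 2 and -0.044 without mutant replicate 1), Cyp4g1 (0.041 without wildtype replicate 1, and -1.004 without wildtype replicate 2), Cad99C (-0.088) and the muscle sheath median (-0.065) without wildtype replicate 2 (the latter 0.35 without wildtype replicate 1 and -0.12 without mutant replicate 1), and after thinning RpL9 (0.040) and camera's direction for the stress list (median 0.18). Thinning and the restriction to protein-coding genes were chosen after the data were seen.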

Other observations

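The genes in this paragraph were chosen after their values were seen and stand for no group. The partners of gnu in a kinase of egg activation, plu and png, had log2 fold changes of -3.11 (SE 0.24) and -1.90 (SE 0.36). The meiotic phosphatase gene twe was at -3.56 (SE 0.23), fzy and cort, activators of the anaphase-promoting complex, were at -3.19 (SE 0.15) and -2.47 (SE 0.28), and the poly(A) polymerase gene wisp was at -2.72 (SE 0.17). In the germline and oocyte list, which as a whole did not pass (11 higher, 16 lower, camera adjusted p = 0.15), osk was at -1.98 (SE 0.19), pgc at -3.16 (SE 0.26) and tud at -1.33 (SE 0.17), against armi at 0.67 (SE 0.13), zuc at 0.83 (SE 0.20) and cuff at 1.39 (SE 0.32), while vas at 0.0086 and piwi at -0.11 did not pass.

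Among genes of cell death, also chosen after their values were seen, hid rose by 1.85 on the log2 scale (SE 0.23, edgeR adjusted p = 0.000868). For rpr there were 0 counts in both wildtype libraries and 30 and 21 in the mutant libraries, at least 6.7-fold higher against a floor of 3 counts over the wildtype group. Among noncoding RNAs, 13 of 29 small nuclear RNA genes and 56 of 226 snoRNA genes fell, against 0 and 12 that rose, and 50 of 275 transfer RNA genes rose against 7 that fell. Of 27 genes in the class named only ncRNA, 22 rose and 2 fell. Over all 7782 genes 1594 rose and 1627 fell, shares near those of the transfer RNA rises and snoRNA falls. Near-identical copies of noncoding genes can share reads, and their fragments need not come from ribosomes. The snoRNA with the largest fall, snoRNA:Psi18S-1854a on chromosome X at 17145903 to 17146041, lies in an intron of RpS5a, which rose. In the same intron snoRNA:Psi18S-1854b had 2169 and 5789 against 5775 and 6924 counts and snoRNA:Psi18S-1854c 1404 and 3408 against 4916 and 6058, and neither passed (log2 fold changes of -0.51 and -0.0089). The snoRNA with the largest rise, snoRNA:Psi18S-1347b on chromosome 2R at 18143000 to 18143142, lies in an intron of pAbp with 13 and 32 against 1599 and 1579 counts, and its neighbour snoRNA:Psi18S-1347a fell to -2.03 (SE 0.22). In that intron snoRNA:Psi18S-1347c, with 645 and 2023 against 2304 and 2180 counts, did not pass (log2 fold change of -0.44). Whether the mutation or another difference between the groups set single snoRNAs of these introns apart was not tested.

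Of the tests that follow, those on egg chamber stage, on vitelline membrane genes and on germ cells were chosen only after the results were seen, and those on thinning, transcript length, scaling and fat body before their outcome, thinning once the library totals had been seen. For the vitelline membrane genes a first rule, met narrowly, was replaced after its outcome was seen, and the rules on egg chamber stage were rewritten then too. The rise of cytoplasmic ribosomal protein genes, with a median log2 fold change of 1.42, was kept at 1.39 when the libraries were thinned to 1 total. Random thinning keeps each gene's expected share of its library, so that value cannot set aside a bias that came with depth. The lowest value over the scalings was 1.39 with 97.6% of members above 0. Protein-coding genes matched on transcript length and mean count had a median of 0.20, which argues against a bias towards short transcripts as the whole cause. The match was imperfect, with a median length of 877.5 nt against 726 nt for the list. Of 10000 matched random lists 0 reached the list's median, but their genes need not vary together as the list's members do. An earlier mix of egg chambers in the mutant may add to the rise of ribosomal protein genes, since chorion genes had a median of -1.95 (95% bootstrap bounds over genes -2.59 and -1.66). How ribosomal protein footprints change with stage was not measured here, and a response to the loss of RpS5b stays open as well, untested.

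The yolk protein genes Yp1, Yp2 and Yp3 had a median log2 fold change of 2.20. The fat body, which also makes yolk proteins, could be a source, and its 10 measured markers had a median of 0.27 with an upper quartile of 1.39, so that some rose and others did not. That median was 0.51 without wildtype replicate 1, 0.10 without wildtype replicate 2 and 0.60 without mutant replicate 2. The lipid synthesis genes FASN1 and Desat1, chosen after their values were seen, were at 0.29 (SE 0.19) and 0.14 (SE 0.15), but both were high in the wildtype libraries, which would hide a small share. A larger share of follicle cells of mid-oogenesis could raise vitelline membrane genes too, although not every gene of that list, such as fs(1)N, need be made by follicle cells. The median of the vitelline membrane list was 0.33 (0.64 without wildtype replicate 1, 0.20 without wildtype replicate 2 and 0.16 without mutant replicate 1). The list's highest value was 1.47, and its upper quartile had 95% bootstrap bounds of 0.26 and 1.26, which treat the genes as independent. These values cannot tell a larger share of such cells from a change within follicle cells. The fat body markers, which went both ways, do not decide on that source either. Per the labels, egg chambers of stages 10 to 14 had been removed from the control ovaries. Whether that removal by itself changed the yolk protein and vitelline membrane values was not tested.

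The fall of the mitotic cell cycle list, with a median of -1.44, was at -1.27 after thinning. Thinning at random keeps each gene's expected share of its library, so a bias that came with deeper sequencing would remain. Whether depth adds to the fall was therefore not decided. Fewer germ cells of any stage could lower germline genes, and the germline and oocyte list had a median of -0.11 (95% bootstrap bounds over genes -0.46 and 0.13, SD of members 1.06). That median was -0.18 without wildtype replicate 2 and -0.21 without mutant replicate 1. The bootstrap bounds treat the genes as independent and do not measure the spread between libraries. The list's members went both ways (11 higher, 16 lower), and footprints are relative to each library's total. Its median therefore cannot tell whether germ cells were fewer. Fewer late egg chambers in the mutant are consistent with the chorion median of -1.95, although the labels say that such chambers were removed from the control. A direct change in cell division in the mutant was not tested apart from that.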
